A study of Mus musculus with 12 samples.

How the data were processed

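The data were 12 RNA sequencing libraries of sorted mouse B cells in 6 groups of 2. Each library was made from polyA RNA of a pool of 2 to 8 C57BL/6 mice, so n = 2 pools per group throughout. Per the labels, germinal centre (GC) B cells were taken on day 12 (Myb experiment) or day 7 (Moz experiment) after immunisation with NP-KLH in alum, and plasmablasts (PB) on day 5 after a boost. The Myb knockout carried floxed Myb alleles with CD23-cre and its control carried the floxed alleles without cre, so the presence of cre is confounded with the loss of Myb. The Moz knockout carried floxed Moz alleles (gene symbol Kat6a) with a cre transgene, and its control carried the same cre alone. The pools held 5, 5, 13, 9, 11 and 14 mice in total for Myb control GC, Myb knockout GC, Myb control PB, Myb knockout PB, Moz control GC and Moz knockout GC.

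The unit is the raw gene count deposited by the authors: 27179 Entrez gene IDs, counted with featureCounts on mm10 per the submitters' processing notes. The aligner, the strand setting and the featureCounts version are not given in the sources used here. The counts of each library in its own table equalled those in the table of the whole series, with 0 genes differing, and 0 columns were left unmapped. A RefSeq annotation of the same genome build gave symbols and coordinates for 25275 IDs, and 1904 IDs had no symbol. Of the IDs with a symbol, 260 are immunoglobulin genes.

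Which groups were compared, the fit, the filter, the lists, the naming rule and most of the other settings were fixed before the data were examined. One model in edgeR 4.0.16 (R 4.3.3) held all 12 libraries with 6 group means, which leaves 6 residual degrees of freedom. Genes passed filterByExpr (minimum count 10, minimum total 15), which kept 13131 IDs, 250 of them immunoglobulin genes. Libraries were scaled by TMM. TMM factors were 0.392 to 0.450 in PB and 1.45 to 1.73 in GC B cells, since immunoglobulin transcripts fill most of the PB libraries. Tests were two-sided quasi-likelihood F tests with robust estimation, with the Benjamini-Hochberg adjustment over the tested genes of 1 comparison and a limit of 0.05. The common dispersion was 0.0486, a biological coefficient of variation of 0.221. Replicates differed far beyond counting noise (chi-square per degree of freedom 26.3 to 97.5). Means are TMM-normalised CPM with the SD of 2 libraries. Unscaled CPM divides by the total count alone. SE is the standard error of a log2 fold change.

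Per the labels, knockout and control pools with the same replicate number were made on the same experiment dates, so the numbers pair the samples. Deviations from the group mean of same-numbered pools correlated at 0.600 in Myb GC B cells, 0.453 in Myb PB and 0.361 in Moz GC B cells. A fit also set in advance therefore takes the replicate number within each experiment as a block ("the fit with the date"), which leaves 3 residual degrees of freedom. PB and GC B cells were not sorted on shared dates, so date and cell type cannot be separated there. The correlation of same-numbered control pools between the cell types was 0.247.

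The 23 fixed lists held 377 entries: GC B-cell identity, light zone, dark zone, cell cycle, plasma cell programme, unfolded protein response, T-bet and type 1 programme, interferon response, migration and adhesion, memory B cell, apoptosis and survival, published c-Myb targets, MOZ complex and targets, immunoglobulin constant regions, naive follicular markers, markers of T cells, of myeloid cells, of NK and plasmacytoid dendritic cells and of erythroid cells, neighbours of Myb, of Kat6a and of Fcer2a (CD23, whose promoter drives the cre), and sex-linked genes. Of the symbols, 3 were missing from the annotation (P2ry8, Hbb-bt, Ahsp). Lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, again with the correlation estimated from the data, and with fry, adjusting over the lists of 1 comparison. Counts of called members are given over all genes and adjusted over the list alone. With 2 pools against 2, no permutation test of labels can pass, since the smallest exact p is 0.333.

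Genes were named by a rule: the deleted gene; the 10 largest folds in each direction (5 for the difference of effects and for PB against GC) among called genes with an average log2 CPM of at least 2 and groups that do not overlap, leaving out immunoglobulin and T cell receptor segments, Xist, Y-linked and provisional symbols; up to 4 members of each list that passed or had at least 2 called members; and always Tbx21, Cxcr3, Cxcr4, Prdm1, Bcl6, Myc and Bcl2. Some further genes that the rule selects are not reported here. Where fewer than 5 genes passed, the 5 smallest p are given as not passing. Names outside this rule were chosen after their values were seen: genes named from the fit with the date, Cd9 and Bhlha15 in the Myb GC comparison, variable segments, genes shared between comparisons, structural RNAs, Ddx3y and Eif2s3y, and 2 IDs without a symbol. For a gene with 0 counts in a group, the fold is printed as "at least", with a floor of 3 counts over that group. With 1 to 3 counts it is a ratio with an exact 95% Clopper-Pearson interval. Such floors and intervals cover counting error only, and the fitted fold of such a gene depends on the prior count.

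Constant region shares were computed per library as the percentage of heavy chain constant counts (or light chain constant counts) that fell on a gene. To ask whether plasmablast RNA in a GC sort could carry a difference, the needed share was taken per gene as knockout minus control, over a mean level in PB, for each replicate number, all in TMM-scaled CPM. It is thus a percentage of the scaled PB level and not of counts. That level came from Myb knockout PB for the Myb genes and, since the Moz experiment has no PB, from Myb control PB for the Moz genes. The same share was taken for the 30 most abundant non-immunoglobulin transcripts, ranked by the PB level used in each case. Only transcripts at least 4 log2 units higher in Myb control PB than in Myb control GC B cells were eligible. The share was also taken for members of the plasma cell and unfolded protein response lists (set against the abundant transcripts outside the list), and for the sum of all immunoglobulin counts. To ask whether male mice could carry the Myb GC increases, as many genes as had risen were picked by the difference between the pools of date 1 alone and read in the all-female pools of date 2. For Moz, as many genes as had risen with the date were picked on date 2 and read on date 1, when both pools had the same label. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used.

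In a self-test, counts were simulated with 200 changed genes per comparison. For Myb GC, 70 of 98 genes changed 4-fold (71.4%) and 16.3% of those changed 2-fold were recovered, all in the right direction, with 7 false among 93 calls. Myb PB gave 73.2% and 21.0% with 6 false of 98, and Moz GC 79.4% and 14.1% with 12 false of 103. With a simulated date effect (SD 0.3 log2 units) in Myb GC, recovery was 59.8% and 1.02% without the block, with 0 false of 59 calls, and 69.1% and 10.2% with the block, with 9 false of 86. In Myb PB it was 37.1% of those changed 4-fold without the block and 58.8% with it, and in Moz GC 67.3% and 76.5%. For the difference of the Myb effects under that date effect, the fit without the block made 0 calls and the fit with it 44, of which 4 were false. Without the low-count filter 30.0% of Myb GC calls were false without a date effect and 12.7% with it, and with DESeq2 16.7% and 6.17%. A raised list passed under both correlations in every comparison, and 0 of 19 other lists passed, except 1 of 19 at the preset correlation in the difference of effects. For these list tests genes were drawn independently and without a date effect. They therefore cannot show how the preset correlation performs where genes move together. In the Myb GC data the estimated correlation was 0.248 for the plasma cell list and 0.451 for the cell cycle list.

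Settings varied by plan were each replicate left out in turn, immunoglobulin genes left out, no filter, a stricter filter (CPM of 5 in at least 2 libraries), the block, median-of-ratios size factors, no robust estimation, the compared groups alone, DESeq2 1.42.0, limma-voom, and the other list tests. Added after seeing the data were limma-voom with the block, IDs without a symbol left out, X and Y genes left out, the naming rule applied to the fit with the date, and list tests with the block and an estimated correlation. Reads, junctions and exon-level coverage were not analysed here.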

Results

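The 12 libraries held 8285934 to 24801297 counts. Pools 1 and 2 had 8825205 and 8285934 in Myb control GC B cells and 9963612 and 9275557 in Myb knockout GC B cells. Plasmablast pools had 24775050 and 20103169 (control) and 19027311 and 22259138 (knockout). Moz GC pools had 18687202 and 24801297 (control) and 14850655 and 21807036 (knockout). Between 10816 and 12368 genes had at least 10 counts. Cell type gave the largest separation, with 82.3% of the variance on the first principal component, 4.32% on the second and 3.47% on the third. Immunoglobulin transcripts made up 66.7 ± 2.38% of counts in control and 69.3 ± 0.97% in Myb knockout plasmablasts (SD, n = 2 pools in each group). In GC B cells they made up 1.70 ± 0.154% and 2.90 ± 0.186% (Myb control and knockout) and 6.54 ± 0.686% and 8.96 ± 0.275% (Moz control and knockout). Mitochondrial transcripts were 4.76 to 6.66% of counts in GC B cells and 0.747 to 1.80% in plasmablasts.

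Transcripts of the deleted genes were counted in every library. Myb (gene ID 17863, mm10 chr10 21124930 to 21160984), the transcription factor deleted by CD23-cre, had 22.8 and 17.3 unscaled CPM in the control GC pools and 22.6 and 18.3 in the knockout GC pools. Plasmablasts had 1.86 and 1.84 (control) and 1.26 and 1.21 (knockout). Moz GC pools had 23.9 and 16.9 (control) and 25.7 and 17.3 (knockout). For Kat6a (ID 244349, chr8 22859442 to 22943259), which encodes the histone acetyltransferase MOZ, the values were 130 and 106 in Moz control and 104 and 139 in Moz knockout pools. After scaling, Myb was 12.3 ± 0.992 CPM in knockout against 12.8 ± 1.78 in control GC B cells (log2 -0.05, SE 0.24). In plasmablasts it was 3.11 ± 0.0115 against 4.39 ± 0.362 CPM (log2 -0.49, SE 0.29). Kat6a was 80.0 ± 19.3 against 77.7 ± 6.11 CPM (log2 0.04, SE 0.38). The edgeR adjusted p was 1 for each. Which exons were floxed is not given in the sources used here, and counts over a whole gene include parts outside a deletion, so these values check nothing about the knockouts. The Y-linked genes Ddx3y and Eif2s3y had 67.2 and 54.1 unscaled CPM in Myb knockout GC pool 1, which is labelled as 2 females. They had 17.7 and 18.7 in control GC pool 1, which is labelled as 1 male and 2 females, and at most 0.483 in both second GC pools. In the Moz comparison both first pools are labelled as 5 males and 1 female, and had 108 (control) and 77.4 (knockout) unscaled CPM of Ddx3y and 64.4 and 84.6 of Xist. Knockout pool 2 is labelled as 6 males and 2 females, and the label of control pool 2 leaves its sexes unclear. They had 38.0 and 82.1 unscaled CPM of Ddx3y and 172 and 14.6 of Xist.

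In GC B cells, the comparison of Myb knockout with control asks which transcripts depend on Myb, or on the cre that comes with its loss, 12 days after immunisation. Of 13131 genes, 31 rose and 3 fell in the fit without the date (755 at an unadjusted p under 0.05). Prdm1 (ID 12142, chr10 44437174 to 44528558), which encodes Blimp-1, the factor that drives plasma cell differentiation, rose from 3.62 ± 0.578 to 18.3 ± 4.91 CPM (log2 2.34, SE 0.35, edgeR adjusted p = 0.0248). Cxcr3 (ID 12766, chrX 101731535 to 101734147), a receptor for interferon-induced chemokines, rose from 3.27 ± 0.966 to 19.3 ± 3.64 CPM (log2 2.56, SE 0.35, edgeR adjusted p = 0.0169). Bhlha15, which encodes the secretory cell factor Mist1, rose as well (log2 1.83, SE 0.27, edgeR adjusted p = 0.0248), as did the tetraspanin gene Cd9 (log2 2.39, SE 0.25, edgeR adjusted p = 0.00556).

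Cadm1 (ID 54725, chr9 47530170 to 47862280), an adhesion molecule, rose from 0.360 ± 0.281 to 6.21 ± 2.87 CPM (log2 4.05, SE 0.55, edgeR adjusted p = 0.0169). The interleukin 13 receptor gene Il13ra1 (ID 16164, chrX 36112108 to 36171262) rose from 0.220 ± 0.0836 to 2.38 ± 0.165 CPM (log2 3.37, SE 0.48, edgeR adjusted p = 0.022). The control levels of Cadm1 and Il13ra1 are near the floor, so the size of these 2 folds is uncertain. The naming limit on average log2 CPM was taken over all 12 libraries and not over the GC pools alone. The adhesion receptor gene Adgrl2 (ID 99633, chr3 148815586 to 148989096) rose from 2.79 ± 0.406 to 23.0 ± 7.11 CPM (log2 3.04, SE 0.37, edgeR adjusted p = 0.0141). Chst1 (ID 76969, chr2 92599632 to 92615252), a carbohydrate sulfotransferase, rose from 8.80 ± 0.784 to 67.8 ± 12.3 CPM (log2 2.95, SE 0.28, edgeR adjusted p = 0.00419). Faxc (ID 76132, chr4 21930906 to 22001461) had 47 counts in knockout against 3 in control pools, a ratio of 13.1 (95% interval 4.23 to 66.0; edgeR adjusted p = 0.0169). Prg2 (log2 2.90, SE 0.43) and the interferon-inducible Ifi211 (log2 2.81, SE 0.48) also rose. So did the carboxypeptidase gene Cpd (log2 2.71, SE 0.41) and the tensin gene Tns3 (log2 2.64, SE 0.43; edgeR adjusted p from 0.0248 to 0.0391 for these 4). Cdc14b (ID 218294, chr13 64192545 to 64274988), a phosphatase gene, fell from 38.8 ± 1.10 to 18.5 ± 0.306 CPM (log2 -1.07, SE 0.19, edgeR adjusted p = 0.0486). The other genes that fell are IDs 19791 (log2 -3.25, SE 0.52) and 100861531 (log2 -3.12, SE 0.51; edgeR adjusted p = 0.035 for each), which have no symbol here. ID 100861531 took 4.11 ± 0.567% of all counts in control and 0.50 ± 0.0545% in knockout GC B cells. Moz control and knockout GC B cells had 0.405 ± 0.0184% and 0.422 ± 0.0366%, so the Myb control pools stand apart, and whether they were prepared differently was not tested.

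With the date as a block, the same comparison called 266 genes higher and 52 lower in edgeR (1533 at an unadjusted p under 0.05). Tbx21 (ID 57765, chr11 97098007 to 97115331) encodes T-bet, the factor of type 1 responses. It had 16.8 ± 4.69 CPM in knockout and 3.57 ± 0.486 in control pools. It rose in this fit (log2 2.22, SE 0.20, edgeR adjusted p = 0.000197) but did not pass without the date (log2 2.23, SE 0.45, edgeR adjusted p = 0.088). Over all settings tried its adjusted p ran from 6.29e-08 (no low-count filter in edgeR) to 0.627 (without control pool 2). Irf1, a factor of interferon signalling, rose in this fit too (log2 1.47, SE 0.13, edgeR adjusted p = 0.000163). Without the date its edgeR adjusted p was 0.103. Gabra4 (log2 3.68, SE 0.69), Rps6ka2 (log2 3.14, SE 0.70), Lag3 (log2 3.10, SE 0.51) and Socs2 (log2 2.85, SE 0.51) were among the largest further increases (edgeR adjusted p from 0.0129 to 0.0394). Lars2 (log2 -1.96, SE 0.32), Chac1 (log2 -1.56, SE 0.31), Nfil3 (log2 -1.19, SE 0.23) and Igf2bp3 (log2 -1.10, SE 0.17) fell in this fit (edgeR adjusted p from 0.00636 to 0.0246). Cxcr4 (log2 -0.04, SE 0.25), Bcl6 (log2 -0.32, SE 0.29), Myc (log2 0.07, SE 0.24) and Bcl2 (log2 0.43, SE 0.55) did not pass without the date, each with an edgeR adjusted p of 1.

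By list, plasma cell genes moved upward in Myb knockout GC B cells, with 18 of 20 estimates positive (camera adjusted p = 9.32e-11; adjusted p = 0.15 with an estimated correlation). Of these 20, Prdm1 rose without the date, and 4 rose adjusted over the list alone. With the date 7 rose (11 adjusted over the list alone), among them Creb3l2 (log2 2.07, SE 0.25), Ly6c2 (log2 1.38, SE 0.22) and Fkbp11 (log2 2.47, SE 0.45). The T-bet and type 1 list did likewise (16 tested, camera adjusted p = 1.59e-07; adjusted p = 0.15 with an estimated correlation). Cxcr3 rose in it without the date (5 rose adjusted over the list alone), and 6 rose with it, including Fcrl5 (log2 1.66) and Itgax (log2 1.79). Interferon response genes had 22 of 23 estimates above 0 (camera adjusted p = 6.45e-13; adjusted p = 0.067 with an estimated correlation). None passed without the date (1 adjusted over the list alone) and 4 rose with it (15 adjusted over the list alone): Zbp1 (log2 0.98, SE 0.12), Gbp7 (log2 1.76, SE 0.33), Ifih1 (log2 1.59, SE 0.32) and Gbp2 (log2 0.85, SE 0.19). For the unfolded protein response the camera adjusted p was 8.49e-06 over 18 genes (adjusted p = 0.28 with an estimated correlation). Without the date 0 of them were called, over all genes or adjusted over the list alone. With it 4 rose, Creld2 (log2 1.08, SE 0.16), Hsp90b1 (log2 1.25, SE 0.19), Pdia4 (log2 0.93, SE 0.17) and Manf (log2 0.66, SE 0.14). All 30 abundant plasmablast transcripts used for comparison were higher in knockout than in control GC pools on both dates. The median rise was 1.27% (pair 1) and 1.34% (pair 2) of their scaled level in knockout plasmablasts. These 30 were selected partly for low levels in the same Myb control GC pools, which favours a rise. For members of the plasma cell list the medians were 0.733% and 0.869%, and for the unfolded protein response 1.59% and 1.87%.

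Immunoglobulin genes also gained counts in Myb knockout GC B cells, together by 0.442% (pair 1) and 0.315% (pair 2) of their scaled level in knockout plasmablasts, alongside the rise of the 30 abundant plasmablast transcripts. Of the 31 genes that rose, 7 were variable segments, and 42 immunoglobulin genes rose with the date. Constant regions passed as a list (12 tested, camera adjusted p = 0.00343; adjusted p = 0.265 with an estimated correlation), with 0 members called over all genes and 2 adjusted over the list alone. Ighg2c is the IgG2c heavy chain gene, and switching to it is driven by T-bet. It had log2 2.27 (SE 0.42, edgeR adjusted p = 0.0683) and rose with the date (log2 2.31, SE 0.29, edgeR adjusted p = 0.00205). Igkc rose with the date as well (log2 1.14, SE 0.21, edgeR adjusted p = 0.0164). Ighg2c held 1.94 ± 0.478% of heavy chain constant counts in control and 6.19 ± 0.897% in knockout GC pools, and Ighg1 17.2 ± 0.399% and 8.11 ± 3.50%.

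GC identity genes leaned downward as a list, with 4 of 18 estimates positive (camera adjusted p = 0.0101; adjusted p = 0.252 with an estimated correlation). Without the date none passed singly, over all genes or adjusted over the list alone. With it 0 passed over all genes, and 1 was lower adjusted over the list alone. This list call was lost without knockout pool 1 (camera adjusted p = 0.447) or control pool 2 (0.11), and that of constant regions without control pool 1 (0.144). Markers of NK and plasmacytoid dendritic cells moved upward alongside the plasma cell list (7 tested, camera adjusted p = 0.00117; adjusted p = 0.265 with an estimated correlation; 0 called, also adjusted over the list alone), a call lost without knockout pool 1 (camera adjusted p = 0.107). Among them, Nkg7 had 19 counts against 3, a ratio of 5.31 (95% interval 1.56 to 28.0), and Prf1 had log2 1.69 (SE 0.58, edgeR adjusted p = 0.466). Bst2 rose with the date (log2 0.88, SE 0.17, edgeR adjusted p = 0.0211). The light zone list did not pass (17 tested, camera adjusted p = 0.0681), though with the date Ccnd2 rose (log2 0.80) and Cd86 fell (log2 -0.56). Other lists that did not pass were the dark zone (camera adjusted p = 0.851), the cell cycle (0.531), migration (0.879; Cxcr3 higher, also adjusted over the list alone), memory (0.22) and apoptosis (0.401). Published c-Myb targets (camera adjusted p = 0.851), MOZ targets (0.884), naive markers (0.211), T cell markers (0.333) and myeloid markers (0.192) did not pass either. The same holds for the neighbours of Myb (camera adjusted p = 0.377), Kat6a (0.193) and Fcer2a (0.228), and for sex-linked genes (0.765). Some of these lists passed with 1 pool left out. Without knockout pool 1 these were naive markers (camera adjusted p = 3.78e-05), the cell cycle (0.0322) and, turned in direction, memory (0.00139) and sex-linked genes (0.00815). Without knockout pool 2 they were memory (camera adjusted p = 8e-09), myeloid (0.000258), sex-linked (0.00528) and T cell genes (0.0212), and without control pool 1 myeloid (0.00428), memory (0.011), light zone (0.0439) and sex-linked genes (0.0497). For naive markers the median (log2 -0.09) and mean (log2 0.01) differ in sign. Only 3 erythroid genes were tested, too few for camera, with a median log2 of -0.56. With the date, Fcer2a itself fell (log2 -0.83, SE 0.16, edgeR adjusted p = 0.0251), as did S1pr3 (log2 -0.77, SE 0.13), and the memory genes Il9r (log2 1.21, SE 0.16) and Tle3 (log2 0.53, SE 0.12) rose. Structural RNAs with a symbol did not pass without the date: Rn7sk had log2 -2.24 (SE 0.46, edgeR adjusted p = 0.0943), Rmrp -1.26, Rpph1 -0.98, mt-Rnr1 -0.81 and mt-Rnr2 -0.80. Whether IDs 19791 and 100861531, which fell, are structural RNAs cannot be read from the annotation used here. The median over 48 small nucleolar RNAs was 0.21.

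These calls rest on small groups. Without control pool 1 or control pool 2, 0 genes were called by edgeR (755 and 552 at an unadjusted p under 0.05). Without knockout pool 1, 3 rose, and without knockout pool 2, 39 rose, with 0 lower in each case. With all pools, DESeq2 called 144 higher and 17 lower and limma-voom 10 and 0.

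**Figure D1:**
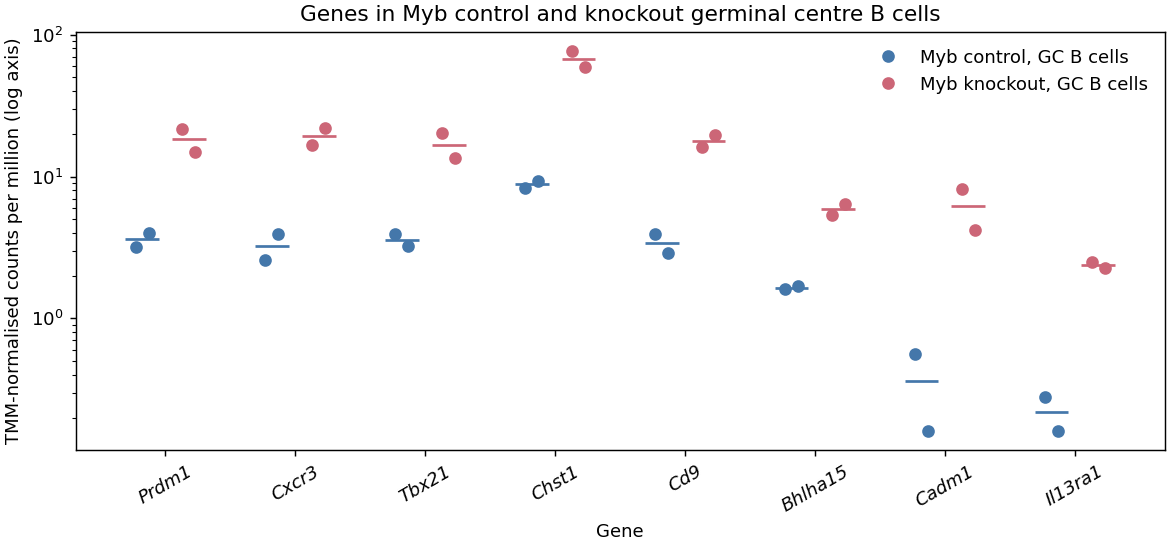
Levels of 8 genes in Myb control (blue) and knockout (red) GC B cells, in TMM-normalised CPM on a log axis; points are pools (n = 2 per group) and lines are means. Tbx21 passed with the date as a block but not in the fit without it (edgeR adjusted p = 0.088).

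In secondary plasmablasts, the same comparison asks what the Myb genotype changes 5 days after a boost. Here 1 gene rose and 4 fell without the date (496 at an unadjusted p under 0.05). Itgb7 (ID 16421, chr15 102215994 to 102233405), which encodes the integrin subunit beta 7 used in homing to the gut, fell from 122 ± 15.2 to 23.2 ± 5.48 CPM (log2 -2.39, SE 0.30, edgeR adjusted p = 0.0167). This call was lost with immunoglobulin genes left out (edgeR adjusted p = 0.068), with the compared groups alone (0.437) and without any 1 plasmablast pool (0.0661 to 0.255), with log2 from -2.66 to -2.13. The others were variable segments: Ighv1-72 (log2 -2.49, SE 0.26), Ighv1-62-3 (log2 -2.82, SE 0.32) and Ighv1-71 (log2 -1.74, SE 0.21) fell and Igkv5-45 (log2 1.46, SE 0.20) rose (edgeR adjusted p from 0.0123 to 0.0271). Tbx21 (log2 1.02, SE 0.57), Cxcr3 (log2 0.58, SE 0.31), Cxcr4 (log2 -0.35, SE 0.25) and Prdm1 (log2 0.29, SE 0.30) did not pass (edgeR adjusted p of 1). Neither did Bcl6 (log2 0.51, SE 0.47), Myc (log2 -0.40, SE 0.26) or Bcl2 (log2 0.40, SE 0.51), each with an edgeR adjusted p of 1.

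With the date as a block, 28 genes rose and 48 fell in plasmablasts (1227 at an unadjusted p under 0.05), and 16 of the 48 were immunoglobulin genes. Ighg1 (ID 16017, chr12 113326541 to 113330523), the IgG1 heavy chain gene, fell (log2 -2.19, SE 0.23, edgeR adjusted p = 0.00116), against an edgeR adjusted p of 0.109 without the date. Its adjusted p ran from 1.27e-11 (DESeq2) to 0.684 (edgeR on the compared groups alone) over the settings. The lambda gene Iglc1 (ID 110785, chr16 19061752 to 19062071) fell as well (log2 -1.49, SE 0.20, edgeR adjusted p = 0.00472), as did Ighe (log2 -0.85, SE 0.16, edgeR adjusted p = 0.0425). Without the date they had an edgeR adjusted p of 0.595 and 0.716. Ighg1 held 38.6 ± 2.96% of heavy chain constant counts in control and 7.93 ± 0.674% in knockout plasmablasts. Ighm held 45.9 ± 5.11% and 76.6 ± 5.12%, and Ighg2c 2.39 ± 0.148% and 6.45 ± 2.95%. Lambda genes (Iglc1 to Iglc3) held 39.4 ± 0.583% of light chain constant counts in control and 14.9 ± 2.67% in knockout plasmablasts. In the corresponding GC B cells they held 45.6 ± 3.72% and 21.1 ± 3.58%.

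Further genes that fell with the date were the lipid transporter gene Abca3 (log2 -2.09, SE 0.14), the protease inhibitor gene Slpi (log2 -1.77, SE 0.19) and Siglecg, an inhibitory receptor of B cells (log2 -1.42, SE 0.13). Faxc (log2 -1.45, SE 0.17), Pik3r5 (log2 -1.29, SE 0.18) and Cdc14b (log2 -1.11, SE 0.15) fell too, and the edgeR adjusted p of these 6 ran from 2.87e-05 to 0.00582. Those that rose included Kit, the receptor of stem cell factor (log2 1.93, SE 0.26), Cadm1 (log2 1.46, SE 0.24), Wnt10a (log2 1.43, SE 0.19), Fam3c (log2 1.29, SE 0.19) and the scavenger receptor gene Cd36 (log2 1.24, SE 0.16), with an edgeR adjusted p from 0.00376 to 0.0164. Calls with the date were shared between the cell types more often than independent draws would give. Higher in both were 16 genes (0.567 expected, one-sided Fisher exact p = 1.25e-20), among them App, Cadm1, Cd36 and Wnt10a, and 6 were lower in both (0.190 expected, one-sided Fisher exact p = 3.1e-08), among them Cdc14b. Genes are not independent and the spread estimates are shared, so these p values are too small.

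By list, cell cycle genes moved upward in Myb knockout plasmablasts (24 tested, camera adjusted p = 5.24e-05; adjusted p = 0.544 with an estimated correlation), and so did dark zone genes (15 tested, camera adjusted p = 0.000387; adjusted p = 0.485 with an estimated correlation). Both calls were lost without knockout pool 2 (camera adjusted p = 0.583 for each), and the dark zone call without control pool 1 (0.0662). No member of either passed without the date, over all genes or adjusted over the list alone. Cdc6 had log2 0.92 (SE 0.24), Ccnb1 0.86 (SE 0.36) and Plk1 0.75 (SE 0.30). With the date 0 members passed over all genes. Adjusted over the list alone, 8 cell cycle genes were then higher and 1 lower, and 6 dark zone genes higher and 1 lower. Migration and adhesion genes moved downward (24 tested, camera adjusted p = 0.000176; adjusted p = 0.265 with an estimated correlation), with Itgb7 lower, also adjusted over the list alone. S1pr1, the receptor for egress, had log2 -0.76 (SE 0.29), and the integrin gene Itgb2 had -0.51 (SE 0.20). Constant regions did not pass (camera adjusted p = 0.0506; 1 higher and 3 lower adjusted over the list alone) but did with the date (camera adjusted p = 0.00184; adjusted p = 0.484 with an estimated correlation). So did sex-linked genes (camera adjusted p = 0.00994 against 0.317 without it; adjusted p = 0.484 with the date and an estimated correlation). Control plasmablast pools 1 and 2 are labelled as 3 males with 3 and 4 females, knockout pool 1 as 3 males and 2 females, and knockout pool 2 as 1 male and 3 females. Xist had 5.53 and 10.7 unscaled CPM in control and 0.526 and 11.9 in knockout pools. Ddx3y had 43.1 and 12.2 in control and 41.6 and 4.85 in knockout pools. Whether sex bears on the plasmablast calls was not tested. The plasma cell list (camera adjusted p = 0.228), the T-bet list (0.205), the interferon list (0.476) and the GC identity list (0.969) did not pass. For GC identity the median (log2 0.04) and the mean (log2 0.01) are positive while the test points down. For apoptosis genes (camera adjusted p = 0.861) the median (log2 -0.03) and mean (log2 0.03) differ. Leaving out single pools left 0 to 2 genes higher and 0 to 2 lower: 2 rose without knockout pool 2 and 2 fell without knockout pool 1, and edgeR called 0 otherwise. With all pools DESeq2 gave 21 higher and 29 lower and limma-voom 2 and 8.

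**Figure D2:**
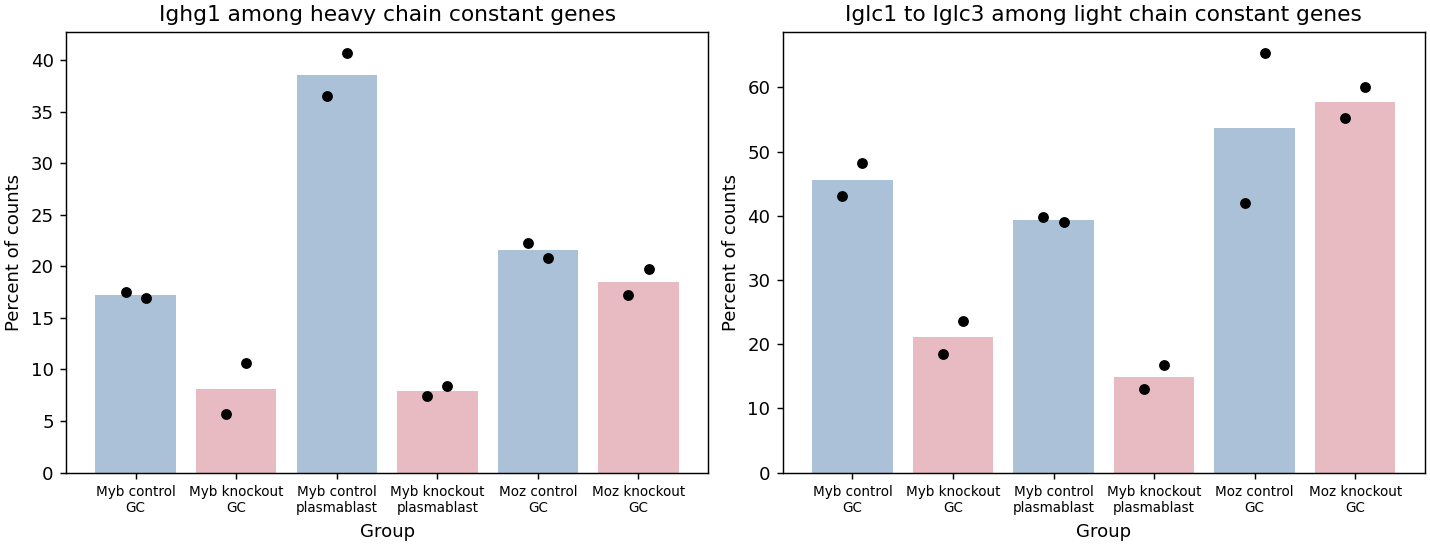
Ighg1 as a percentage of heavy chain constant counts (left) and Iglc1 to Iglc3 as a percentage of light chain constant counts (right) in the 6 groups. Bars are means of 2 pools and dots are pools.

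The difference of the Myb effects asks whether the genotype acts differently in plasmablasts and in GC B cells. Without the date 1 gene passed: Faxc, with 3 counts over the control GC pools, so the size of its fitted difference depends on the prior count. Its effect was lower in plasmablasts (log2 -5.10, SE 0.54, edgeR adjusted p = 0.0145; 489 genes at an unadjusted p under 0.05). This call was lost with limma-voom (adjusted p = 0.297), with the compared groups alone (edgeR adjusted p = 0.0674) and in 6 of 8 fits without 1 pool (0.0544 to 0.219), with log2 from -5.55 to -4.79 in those 6. The next smallest p values did not pass: Cd9 (log2 -2.01, SE 0.33), Bhlha15 (log2 -1.95, SE 0.34) and Itgb7 (log2 -2.28, SE 0.41), each with an edgeR adjusted p of 0.204, and Chst1 (log2 -1.90, SE 0.37, edgeR adjusted p = 0.317). With the date 8 genes had a higher and 63 a lower effect in plasmablasts (1016 at an unadjusted p under 0.05). Among the lower were Itgb7 (log2 -2.26, SE 0.19, edgeR adjusted p = 0.000505), Tns3 (log2 -2.80, SE 0.28, edgeR adjusted p = 0.00134), Slpi (log2 -2.19, SE 0.27, edgeR adjusted p = 0.00444), Cxcr3 (log2 -2.03, SE 0.36, edgeR adjusted p = 0.0354) and Ighg1 (log2 -1.65, SE 0.31, edgeR adjusted p = 0.0444). Plasma cell, secretory and interferon genes were also among them, with Creb3l2 (log2 -2.23), Hsp90b1 (log2 -1.67), Creld2 (log2 -1.21), Irf1 (log2 -1.17) and Zbp1 (log2 -0.95). Prdm1 did not pass in either fit (log2 -2.05, SE 0.40, edgeR adjusted p = 0.112 with the date; 8.76e-05 to 0.964 over all settings), and Tbx21 had log2 -1.21 (SE 0.72) with an edgeR adjusted p of 1 without it.

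As lists, the plasma cell programme (camera adjusted p = 6.48e-12; adjusted p = 0.13 with an estimated correlation) and the unfolded protein response (camera adjusted p = 9.19e-08; adjusted p = 0.189 with an estimated correlation) had lower effects in plasmablasts than in GC B cells. So had interferon genes (camera adjusted p = 5.32e-06; adjusted p = 0.13 with an estimated correlation) and the T-bet list (camera adjusted p = 0.00167; adjusted p = 0.25 with an estimated correlation). The same direction held for constant regions, migration genes and NK markers (camera adjusted p from 5.32e-06 to 0.00304; adjusted p from 0.13 to 0.25 with an estimated correlation). Light zone, cell cycle, dark zone and Fcer2a neighbour genes had higher effects (camera adjusted p from 0.00254 to 0.0278; adjusted p from 0.173 to 0.566 with an estimated correlation). Over all genes 0 members of these lists were called without the date. Adjusted over the list alone, 3 plasma cell genes, 2 constant regions, 2 migration genes, 1 T-bet gene, 1 NK gene and 1 light zone gene were lower and 1 light zone gene was higher. With the date, adjusted likewise, 12 plasma cell genes, 5 constant regions, 4 interferon genes and 2 NK genes were lower and 0 higher. Unfolded protein response genes had 12 lower and 1 higher, T-bet 3 and 1, migration 3 and 1 and light zone 1 and 3. Sex-linked genes did not pass without the date (camera adjusted p = 0.202) and did with it (camera adjusted p = 0.000235; adjusted p = 0.304 with an estimated correlation). Leaving out single pools ended the calls of the T-bet, migration, NK, light zone, dark zone, cell cycle and Fcer2a neighbour lists (highest camera adjusted p from 0.0767 to 0.736).

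In the Moz experiment, the comparison asks which transcripts depend on MOZ in GC B cells 7 days after immunisation. No gene passed without the date in edgeR (315 at an unadjusted p under 0.05), while DESeq2 called 11 higher and 0 lower and limma-voom 0. The smallest p values, none passing (edgeR adjusted p of 1), belonged to 5 genes. Adhfe1 (ID 76187, chr1 9547948 to 9577970) had 2.97 ± 0.495 CPM in knockout against 7.81 ± 1.07 in control pools (log2 -1.40, SE 0.27). Ly6c2 (ID 100041546, chr15 75108161 to 75112066) had 68.0 ± 15.6 against 22.1 ± 6.13 CPM (log2 1.62, SE 0.31). The others were Camk2a (log2 1.07, SE 0.23), Cdh17 (log2 1.33, SE 0.32) and Nfam1 (log2 0.94, SE 0.23). Cxcr3 had log2 1.00 (SE 0.31), Prdm1 0.42, Tbx21 0.25, Bcl2 0.45, Bcl6 -0.19, Cxcr4 -0.14 and Myc -0.04, each with an edgeR adjusted p of 1.

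With the date, 35 genes rose and 4 fell in Moz knockout GC B cells (1339 at an unadjusted p under 0.05), and 12 of the 35 were immunoglobulin genes. Ly6c2, a surface antigen found on many plasma cells, rose (log2 1.63, SE 0.13, edgeR adjusted p = 0.000538), as did Itgb7 (32.2 ± 1.82 to 60.1 ± 6.23 CPM, log2 0.90, SE 0.13, edgeR adjusted p = 0.0169). Transcobalamin 2 (Tcn2, log2 1.56, SE 0.22), the myosin gene Myo1f (log2 1.38, SE 0.16) and the cadherin gene Cdh17 (log2 1.29, SE 0.20) rose too. So did the sodium pump subunit gene Atp1b1 (log2 1.18, SE 0.14) and the cytokine receptor gene Csf2rb (log2 0.99, SE 0.16; edgeR adjusted p from 0.00804 to 0.0408 for these 5). Adhfe1 (log2 -1.40, SE 0.19, edgeR adjusted p = 0.0158), Pfn2 (log2 -1.01, SE 0.16, edgeR adjusted p = 0.0294) and Ccm2 (log2 -0.60, SE 0.10, edgeR adjusted p = 0.0422) fell. Of the genes higher with the date, 15 were also higher in Myb knockout GC B cells with the date (0.709 expected, one-sided Fisher exact p = 6.05e-17), among them Ly6c2, Csf2rb, Plac8 and 7 immunoglobulin genes, and 0 were lower in both. The 2 experiments share no libraries, but the genes are not independent and the spread estimates are shared, so this p value is too small.

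As groups, plasma cell genes moved upward in Moz knockout GC B cells, with 18 of 20 estimates positive (camera adjusted p = 1.27e-07; adjusted p = 0.221 with an estimated correlation; 0 called, 1 higher adjusted over the list alone). Irf4 (log2 0.71, SE 0.26) did not pass singly. The unfolded protein response (17 of 18 positive, camera adjusted p = 0.000127; adjusted p = 0.317 with an estimated correlation) and the interferon response (20 of 23, camera adjusted p = 0.000128; adjusted p = 0.221 with an estimated correlation) pointed the same way. Constant regions (11 of 12, camera adjusted p = 0.00063; adjusted p = 0.221 with an estimated correlation) and migration genes (18 of 24, camera adjusted p = 2.86e-06; adjusted p = 0.115 with an estimated correlation) moved upward too. So did memory genes (camera adjusted p = 4.23e-05; adjusted p = 0.34 with an estimated correlation; Zbtb32 log2 1.06, SE 0.33) and the T-bet list (camera adjusted p = 0.00699; adjusted p = 0.317 with an estimated correlation). Myeloid markers moved with them (camera adjusted p = 0.0145; adjusted p = 0.548 with an estimated correlation), and 2 of these rose adjusted over the list alone. GC identity genes moved downward, with 0 of 18 positive (camera adjusted p = 0.000127; adjusted p = 0.13 with an estimated correlation), for instance Gcsam (log2 -0.55, SE 0.24), Fas (log2 -0.46) and Rgs13 (log2 -0.58). Cell cycle genes did as well (camera adjusted p = 0.00548; adjusted p = 0.548 with an estimated correlation). None of these members passed without the date over all genes, and in the other lists none did adjusted over the list alone. With the date and adjusted over the list alone, 9 plasma cell, 6 migration, 3 T-bet, 2 interferon, 2 myeloid and 1 unfolded protein response genes were higher. Memory genes had 7 higher and 1 lower, constant regions 4 and 1, GC identity 0 and 3 and cell cycle 0 and 0. Neither MOZ targets (camera adjusted p = 0.757) nor light zone (0.864) and dark zone genes (0.117) passed. For the light zone list the median (log2 -0.04) and mean (log2 0.03) differ in sign, as they do for NK markers (camera adjusted p = 0.631; log2 -0.15 and 0.08). For sex-linked genes the median is log2 -0.47 and the mean -0.13 while the test points up (camera adjusted p = 0.939). The neighbours of Kat6a passed with the date (camera adjusted p = 0.0433; adjusted p = 0.355 with an estimated correlation) and not without it (camera adjusted p = 0.0935). Leaving out single pools ended the calls of the plasma cell, unfolded protein response, constant region, T-bet, cell cycle and myeloid lists (highest camera adjusted p from 0.0524 to 0.909). Of 30 abundant plasmablast transcripts 26 (pair 1) and 28 (pair 2) were higher in Moz knockout than in control GC pools, by a median of 1.55% and 3.49% of their scaled level in Myb control plasmablasts. Without knockout pool 1, 3 genes rose, and edgeR called 0 without any other single pool.

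The comparison of plasmablasts with GC B cells of the Myb control mice asks what separates the cell types, although the sorting dates, days and boost differ with them. Of the tested genes, 53.2% differed. In all, 3289 genes were higher and 3695 lower in plasmablasts, 2721 and 2766 of them by more than 2-fold (7663 at an unadjusted p under 0.05). Prdm1 was higher, at 205 ± 45.3 against 3.62 ± 0.578 CPM (log2 5.82, SE 0.38, edgeR adjusted p = 3.28e-07). Sdc1, which encodes the plasma cell marker CD138, was higher too (549 ± 65.7 against 1.36 ± 0.444 CPM, log2 8.63, SE 0.49, edgeR adjusted p = 1.63e-07). Bcl6, the factor that maintains the germinal centre programme, was lower (1.28 ± 0.738 against 133 ± 8.79 CPM, log2 -6.63, SE 0.40, edgeR adjusted p = 2.33e-07). Spib (log2 -7.32, SE 0.33), Bach2 (log2 -5.97, SE 0.27) and the follicle homing receptor gene Cxcr5 (log2 -6.33, SE 0.28) were lower as well, each with an edgeR adjusted p of 8e-08. Cxcr3 was higher (log2 3.07, SE 0.35, edgeR adjusted p = 2e-05) and Bcl2 too (log2 2.71, SE 0.56, edgeR adjusted p = 0.00155). Tbx21 (log2 -1.48, SE 0.53, edgeR adjusted p = 0.0349), Myc (log2 -1.68, SE 0.25, edgeR adjusted p = 0.000154) and Myb (log2 -1.55, SE 0.26, edgeR adjusted p = 0.00039) were lower. The Tbx21 call was lost without any 1 of the 4 pools (edgeR adjusted p from 0.0552 to 0.219), with a stricter filter (0.0502), with immunoglobulin genes left out (0.0503) and with limma-voom (0.0933). Cxcr4 did not pass (log2 0.46, SE 0.25, edgeR adjusted p = 0.136), except with the replicate number as a block (0.0278).

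Among the largest increases, Fkbp11, a protein folding gene, stood at 396 ± 102 against 0.430 ± 0.38 CPM (log2 9.78, SE 0.56, edgeR adjusted p = 1.74e-07). Slc16a5 had 964 counts in plasmablasts and 0 in GC B cells (at least 450-fold higher), Nrg2 396 and 0 (at least 185-fold) and Mt2 354 and 0 (at least 165-fold), while Prlr had 1214 and 3, a ratio of 566 (95% interval 193 to 2750). In the other direction, Hbb-bh1 had 380 counts in GC B cells and 0 in plasmablasts (at least 90.5-fold lower), Pcyt1b 320 (at least 76.2-fold), Aif1l 183 (at least 43.6-fold), Btnl1 161 (at least 38.4-fold) and Ffar1 156 (at least 37.2-fold).

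The lists split by cell type. Of 20 plasma cell genes 19 were higher (camera adjusted p = 5.46e-23; adjusted p = 0.0275 with an estimated correlation, 0.0923 with the replicate number as a block as well). So were 18 of 18 genes of the unfolded protein response (camera adjusted p = 3.99e-18; adjusted p = 0.0566 with an estimated correlation), such as Creld2 (log2 6.24) and Pdia4 (log2 6.40). Of the constant regions, 11 of 12 were higher (camera adjusted p = 5.9e-17), with Ighg1 at log2 8.53 (SE 0.50). Of 18 GC identity genes 17 were lower (camera adjusted p = 1.34e-21). So were 24 of 24 cell cycle genes (camera adjusted p = 5.77e-19; adjusted p = 0.0857 with an estimated correlation), such as Mcm5 (log2 -4.79) and Plk1 (log2 -4.44). Dark zone genes were lower (14 of 15, camera adjusted p = 8.41e-11; adjusted p = 0.0683 with an estimated correlation). Among light zone genes 15 were lower and 2 higher of 17 (camera adjusted p = 2.64e-07; adjusted p = 0.0857 with an estimated correlation), with Cd86 (log2 -3.38) and Il21r (log2 -4.88). Naive markers (6 of 11 lower, camera adjusted p = 0.00479; adjusted p = 0.362 with an estimated correlation) included Fcer2a (log2 -6.03). Of 15 myeloid markers 9 were higher (camera adjusted p = 0.0128; adjusted p = 0.524 with an estimated correlation), among them Ly6c2 (log2 8.88). Adjusted over the list alone these counts were the same. Several lists that did not pass held calls in both directions, such as migration (9 higher and 8 lower of 24, camera adjusted p = 0.905; median log2 0.10, mean -0.09) and apoptosis (5 and 6 of 19, camera adjusted p = 0.74). Others were memory (3 and 6 of 16, camera adjusted p = 0.461) and published c-Myb targets (3 and 8 of 14, 3 and 9 adjusted over the list alone, camera adjusted p = 0.165). T-bet genes had 4 higher and 2 lower of 16 (camera adjusted p = 0.856), with a median log2 of -0.19 and a mean of -0.11 while the test points up.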

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

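The tests on the needed share of the plasmablast level in the Myb comparison and for lists and immunoglobulin in both comparisons, on male mice, on cre, on clones and on the abundant transcripts in the Moz comparison were chosen only after the results were seen; the test of the needed share of the Moz genes was set before that share was computed, when the shares of the abundant transcripts were already known.

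The Myb effect differed between the cell types for Faxc, by -5.10 (log2) in the fit without the date, a call lost with limma-voom, with the compared groups alone and in 6 of 8 fits without 1 pool. With the date Faxc differed by -5.08, Fkbp11 by -2.95, Socs2 by -2.87, Tns3 by -2.80 and Ifi211 by -2.79, all with the lower effect in plasmablasts. Faxc had 3 counts over the control GC pools, so the size of its difference depends on the prior count. Fkbp11 was also low in those pools. The effect was higher in plasmablasts for Chac1 (2.07), Parm1 (1.82), Fam3c (1.26) and Fcmr (1.02). The cause was not tested for any of these genes singly, and a difference in how Myb acts in the 2 cell types stays open.

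Among the 24 non-immunoglobulin genes that rose in Myb knockout GC B cells, plasmablasts carried over into the sort are 1 candidate explanation. Over all 24 the needed share of the scaled plasmablast level had a median of 21.2% in pool pair 1 and 16.8% in pair 2, above the highest share of the 30 abundant plasmablast transcripts (11.1% and 8.06%, set by Chst1, itself 1 of the genes; medians 1.27% and 1.34%). This is not consistent with carry-over of plasmablasts like those sorted here as the sole source of the set. It stays open for single genes such as Prdm1 and Bhlha15, and plasmablasts of another kind were not tested. The 24 genes were called on these same pools, which favours a high needed share. The number of male mice was tested on 31 genes picked by the largest difference in pool pair 1 alone, 16 of them called. In pair 2, which was all female, 29 of the 31 were more than 1 log2 unit higher, against 2.68% of all genes, which is not consistent with male number as the cause. With 0 Myb control libraries carrying cre, an effect of the CD23-cre transgene cannot be told from the loss of Myb.

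The same carry-over might raise the plasma cell and unfolded protein response lists and the immunoglobulin genes in Myb knockout GC B cells. All 30 abundant plasmablast transcripts were higher on both dates, although they were selected partly for low levels in the same control GC pools. Members of the plasma cell list needed a median of 0.733% (pair 1) and 0.869% (pair 2), below the middle range of the 23 abundant transcripts outside the list (1.08 to 1.93% and 1.03 to 1.88%). Members of the unfolded protein response needed 1.59%, within the range of the 20 outside that list (0.638 to 1.89%), and in pair 2 1.87%, above it (0.843 to 1.68%). Immunoglobulin counts together needed 0.442% and 0.315%, less than the middle range of the 30 (0.808 to 1.85% and 0.911 to 1.91%) and more than the lowest of them (0.072% and 0.0641%). Carry-over would raise all plasmablast transcripts by about the same share. The immunoglobulin share lay below both list medians. It also lay below the middle range of the unfolded protein response members (0.989 to 1.95% and 1.30 to 2.29%). The test against the abundant transcripts gave no verdict for the unfolded protein response, whose median lay within their range in pair 1 and above it in pair 2. With the lower immunoglobulin share, carry-over of plasmablasts like those sorted here is not shown as the sole source of that list's shift. Carry-over stays open as a part of that shift, and for the plasma cell list and immunoglobulin. A rise of these transcripts within GC B cells after loss of Myb also stays open.

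In Myb knockout plasmablasts the Ighg1 and lambda shares were lower. Clones that differ from pool to pool might lower a share by chance. For Ighg1 the smallest difference over the 2 pairs of pools was 29.0 points (largest 32.3), against at most 4.95 between pools of 1 group. The gap was thus larger than any within the 6 groups. With 2 pairs, and 1 difference per group to set them against, it cannot exclude that explanation. For lambda the smallest was 22.2 points (largest 26.8), against 23.3 between the Moz control pools, which leaves it open, although the pairs of Myb GC pools differed in the same direction by 24.5 and 24.7 points. Loss of Myb itself stays open for both.

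For the genes higher in Moz knockout GC B cells with the date, carried over plasmablasts might again contribute. Measured against Myb control plasmablasts, since the Moz experiment has none, the 23 non-immunoglobulin genes needed a median of 19.4% (pair 1) and 18.4% (pair 2), above the highest abundant transcript (3.51% and 9.18%; medians 1.55% and 3.49%), which is not consistent with carry-over of plasmablasts like those sorted here as the sole source. The 23 genes were called on these same pools, which favours a high needed share. Of the 30 abundant transcripts 1 (Slpi) was at or below 0 on both dates. A rise of a part of these transcripts within GC B cells can thus neither be shown nor dismissed. Set against the abundant transcripts alone, the medians of both lists lay in the range that carry-over would give. Members of the plasma cell list needed a median of 1.30% and 2.70%, within the middle range of the 23 abundant transcripts outside the list (1.10 to 2.28% and 2.53 to 4.36%). Members of the unfolded protein response needed 1.57% and 3.76% (0.998 to 1.95% and 1.33 to 4.28% for the 20 outside it). Immunoglobulin counts together needed 0.748% and 1.24%, below the middle range of the 30 (1.08 to 2.31% and 1.74 to 4.29%), which leaves carry-over open for them. Carry-over would raise all plasmablast transcripts by about the same share, and the immunoglobulin share fell short of both list medians on both dates. For the lists carry-over therefore stays open as a part of the shifts and is not shown as their sole source. The number of male mice in the pools stays open for the Moz genes. Of 35 genes picked on date 2 alone, 3 were more than 1 log2 unit higher on date 1 (0.388% of all genes were), and a low number is what male number as the cause would give, but 0 of the 35 were among the genes called, so this decides nothing about those. Loss of MOZ itself stays open.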

How the results depend on the processing

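Of the tests of how the processing matters, limma-voom with the block, leaving out IDs without a symbol, leaving out genes on X and Y, the naming rule applied to the fit with the date, and list tests with the block and an estimated correlation were chosen only after the results were seen.

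The number of genes called in Myb GC B cells (31 higher, 3 lower) depended on the model of the date, on the filter and on the tool. With the replicate block it was 266 and 52 (limma-voom with that block 141 and 34), without a low-count filter 295 and 25, with DESeq2 144 and 17, and with limma-voom 10 and 0. With immunoglobulin genes left out 20 rose, and with IDs without a symbol left out 1 fell. With the compared groups alone edgeR called 0 and 0 (510 at an unadjusted p under 0.05). Leaving out 1 pool gave 0 to 39 higher and 0 to 0 lower: 0 without control pool 1 or 2, 3 without knockout pool 1 and 39 without knockout pool 2. Of the 34 calls, 33 were shared with DESeq2, 8 with limma-voom and 31 with the block.

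For Myb plasmablasts (1 higher, 4 lower) the replicate block gave 28 and 48 (with limma-voom 26 and 40), no filter 46 and 58, DESeq2 21 and 29, limma-voom 2 and 8. With immunoglobulin genes left out, or with the compared groups alone, edgeR called 0 and 0 (359 at an unadjusted p under 0.05 in the latter). Leaving out 1 pool gave 0 to 2 higher (2 without knockout pool 2) and 0 to 2 lower (2 without knockout pool 1), and 0 without either control pool.

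For Moz GC B cells (0 in edgeR, 315 at an unadjusted p under 0.05) the replicate block gave 35 and 4 (with limma-voom 40 and 5), no filter 45 and 10, DESeq2 11 and 0, and limma-voom 0. Leaving out 1 pool gave 0 to 3 higher (3 without knockout pool 1) and 0 to 0 lower.

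For the difference of the Myb effects (0 higher, 1 lower) the replicate block gave 8 and 63 (with limma-voom 4 and 27), no filter 13 and 123, DESeq2 8 and 37, limma-voom 0 and 0, and the compared groups alone 0 and 0 (407 at an unadjusted p under 0.05 in edgeR). Leaving out 1 pool gave 0 to 2 higher (2 without knockout plasmablast pool 1) and 0 to 1 lower (0 without any 1 of the GC pools, control plasmablast pool 1 or knockout plasmablast pool 2). For plasmablasts against GC B cells the range was 2758 to 2937 higher and 2795 to 3229 lower, and median-of-ratios size factors gave 3502 and 3409 in place of 3289 and 3695.

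Some lists changed direction when 1 pool was left out. In Myb GC B cells without knockout pool 1, memory genes (camera adjusted p = 0.00139) and sex-linked genes (0.00815) pointed opposite to all pools together. Over the pools left out, the camera adjusted p ran from 8e-09 to 0.726 for memory and from 0.00528 to 0.352 for sex-linked genes. In the difference of effects, leaving out the same pool reversed memory genes (camera adjusted p = 0.0461, range 5.75e-07 to 0.844), myeloid markers (0.0198, range 0.00526 to 0.736) and sex-linked genes (0.0329, range 0.000381 to 0.844). Without Moz control pool 1 myeloid markers reversed (camera adjusted p = 0.722, range 0.000115 to 0.722). The call of the GC identity list in Myb GC B cells was lost without knockout pool 1 (camera adjusted p = 0.447) and control pool 2 (0.11), that of constant regions without control pool 1 (0.144) and that of NK markers without knockout pool 1 (0.107). In Moz GC B cells the plasma cell call was lost without knockout pool 2 (0.158) and the unfolded protein response without control pool 1 (0.343) and knockout pool 2 (0.726). Cell cycle was lost there without knockout pool 1 (camera adjusted p = 0.427) and control pool 2 (0.909), T-bet without these (0.0525 and 0.353) or knockout pool 2 (0.0622), constant regions without knockout pool 2 (0.0524), and myeloid markers without knockout pool 1 (0.427) or 2 (0.0536). In Myb plasmablasts the cell cycle and dark zone calls were lost without knockout pool 2 (0.583 for each), and the dark zone call without control pool 1 (0.0662). In the difference of effects the highest camera adjusted p over the pools left out was 0.736 for cell cycle and 0.651 for dark zone (knockout plasmablast pool 2), 0.155 for light zone and 0.259 for Fcer2a neighbours (control plasmablast pool 1), 0.252 for T-bet and 0.0767 for migration (knockout GC pool 1) and 0.393 for NK markers (knockout plasmablast pool 1). For plasmablasts against GC B cells the myeloid call was lost without control plasmablast pool 1 (0.0809).

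Some lists that did not pass with all pools passed in the same direction with 1 pool left out. The lowest camera adjusted p in Myb GC B cells was 3.78e-05 for naive, 0.000258 for myeloid and 0.0212 for T cell markers, 0.0322 for cell cycle and 0.0439 for light zone, besides memory and sex-linked genes above. In Myb plasmablasts it was 4.82e-05 for constant regions, 0.000435 for myeloid markers, 0.0245 for light zone and unfolded protein response, and 0.0266 for Myb neighbours. In Moz GC B cells it was 0.0124 for T cell markers, 0.0157 for dark zone and 0.0273 for light zone. In the difference of effects it was 0.000185 for naive markers and 0.0111 for GC identity, besides the 3 lists above, and for plasmablasts against GC B cells 0.0474 for interferon genes.

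At the preset correlation the block changed no list call beyond those given with the comparisons. With an estimated correlation, all list calls made at the preset correlation without a block were lost in the knockout comparisons and the difference of effects. These were 7 in Myb GC B cells, 3 in Myb plasmablasts, 10 in Moz GC B cells and 11 in the difference. The same calls were lost with fry, and with a block and an estimated correlation together. Between plasmablasts and GC B cells 6 calls were lost with an estimated correlation. A block as well ended the plasma cell call too (camera adjusted p = 0.0923). Fry lost none there, and 7 further lists passed.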

Other observations

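The shares and Y-linked transcripts in this part were chosen for comparison only after the results were seen, while the edgeR tests were planned; no test of a cause was made.

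The pool of Myb knockout GC B cells from date 1 is labelled as 2 females, yet had 67.2 unscaled CPM of Ddx3y, 54.1 of Eif2s3y and 297 of Xist, against 17.7, 18.7 and 812 in the control pool of the same date, labelled as 1 male and 2 females. The cause was not tested. In the pair of pools from date 2 Ddx3y was at most 0.483 CPM.

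IDs 100861531 and 19791, which have no symbol here, set the Myb control GC pools apart from all other GC pools. The first held 4.11 ± 0.567% of counts in control and 0.50 ± 0.0545% in knockout pools, the second 0.414 ± 0.0372% and 0.0461 ± 0.00177% (SD, n = 2). In Moz control and knockout GC pools the first held 0.405 ± 0.0184% and 0.422 ± 0.0366%, the second 0.0393 ± 0.00161% and 0.0405 ± 0.00245%, close to the Myb knockout pools. Rn7sk had log2 -2.24 in Myb knockout against control (SE 0.46, edgeR adjusted p = 0.0943). The cause was not tested, and a difference in how the RNA of the control pools was prepared would bear on every Myb GC call.

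The share of Ighg1 among heavy chain constant counts was 21.6 ± 0.994% in Moz control and 18.5 ± 1.81% in Moz knockout GC B cells, and that of lambda genes 53.6 ± 16.5% and 57.7 ± 3.47% of light chain constant counts, with 42.0% and 65.3% in the 2 Moz control pools.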
